A study of Mus musculus with 16 samples.

How the data were processed

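The series holds 16 libraries from leukaemic cells of C57BL/6 mice that carried secondary transplants of T cell acute lymphoblastic leukaemia (T-ALL) driven by NOTCH-ΔE, an activated form of the Notch receptor. Mice ate a control diet with 8 g/kg valine, a diet without valine (0 g/kg), or that diet with 0.4 or 0.8 g/kg valine, for 3 weeks. The sample characteristics give valine per kg of diet, whereas the treatment protocol mentions supplementation in drinking water, and the doses follow the sample characteristics here. GFP-positive leukaemic cells were sorted from spleen and gave libraries of total RNA and of ribosome-protected fragments (RPF), the stretches of mRNA that ribosomes shield from nuclease. Each diet had 2 libraries per fraction, labelled T-ALL 2 and T-ALL 3. The labels do not state whether these numbers mark separate primary tumours, separate recipient mice, or both, so p-values measure only the spread between these samples.

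The deposited table gives FPKM, fragments per kilobase of gene scaled to library size, for 12012 genes in all 16 libraries, with replicates kept apart. The submitters' processing notes name cutadapt 1.18, Bowtie2 2.3.4, STAR 2.5.0c and edgeR 3.14.0 with the builds mm10 and GRCm38. The roles of these tools, the counting step, the gene filter and the formula behind the FPKM values are not given in the sources used here. The table lists Ensembl identifiers, of which 7 had no symbol, and 11387 of 12008 symbols were found in the reference gene table (assembly GRCm38.p6), from which gene positions were taken. Reads of closely related genes, among them histones, globins, ribosomal proteins and the pair Hspa1a and Hspa1b, may not be assigned uniquely, so single members of these families are uncertain.

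In each library all values above 0 were whole multiples of 1 read divided by gene length. Reads per gene were recovered from these steps: 100% of 149988 values above 0 were whole within 0.02 reads, with a largest distance of 7.73e-06. The recovery was also tested on simulated data, where 99.9% of 11796 genes came back with their true counts. Recovered reads per library ranged from 41848 to 205545 for RPF and from 364685 to 1269364 for total RNA. A count of 0 was read as up to 3 reads, a share of 0.00146% to 0.00717% of an RPF library and 0.000236% to 0.000823% of a total RNA library. Shares of reads carry 95% Wilson intervals. Intervals and floors cover counting error only, since reads amplified by PCR are not independent molecules.

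Each fraction was fitted with limma 3.58.1 in R 4.3.3 on log2(FPKM + 0.5), with diet as a factor over all 8 libraries, for genes with a mean FPKM of at least 1. Moderation of the variance followed its trend with expression, tests were two-sided, and p-values were adjusted by Benjamini-Hochberg at 0.05 over the genes tested. Standard errors (SE) of log2 changes come from this moderated variance over all 8 libraries and not from the 2 libraries of a diet. Translational efficiency (TE) was the difference of the RPF and total RNA log2 values with the same diet and T-ALL number, fitted in the same way over genes that passed the filter in both fractions. Every diet was compared with 8 g/kg, so the 3 comparisons of a fraction share their 2 control libraries. An exact permutation test of 2 against 2 samples cannot give a p-value below 0.333, so none was run, and single genes were tested with limma's moderated variance.

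Changes of 35 gene lists were tested against all other tested genes with limma's camera at an inter-gene correlation of 0.01, for lists with at least 5 tested members, with p-values adjusted over the lists of a comparison. The lists cover respiratory chain complexes, their assembly factors and mtDNA-encoded subunits. They cover ribosomes, translation factors, the ATF4 amino acid response, tRNA synthetases, amino acid transport and catabolism, central metabolism and cholesterol synthesis. They also cover the cell cycle, histones, Notch targets, T cell identity, stress and immediate early responses, protein degradation, and markers of other cell types of the spleen. Fits, lists, alternatives and the rule for named genes were fixed before the data were examined.

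Genes were named by that rule. It takes up to 10 genes per direction with the largest change past the test and the same sign in both T-ALLs. Where fewer passed, it fills up to 5 per direction with the smallest unadjusted p among genes with an absolute log2 change of at least 1, and these are described as not past the test. It adds up to 4 members of each list that passed, up to 2 members of each other list, and a fixed set of genes of the amino acid response, valine handling, Notch signalling, the respiratory chain and other cell types. Cd79a, in the fixed set, was not analysed here, and some genes that the rule takes are not reported here.

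A fold against a group with 0 reads in both libraries was computed against 3 reads over the group and is written as a lower bound. It bounds only the group with 0 reads and takes the reads of the other group as exact. Where that other group has few reads, the bound does not exclude a smaller fold. Alternatives fixed in advance changed the pseudocount to 0.1 or 1, the filter to a mean FPKM of 5 or none, the scaling between libraries, the variance trend, the inter-gene correlation (estimated from the data), the contrast, and the pairing of fractions. They also added the T-ALL number as a covariate and left out each library in turn. In the latter the remaining single library was assumed to vary like the other groups. Another 3 alternatives were chosen after seeing the data: a minimum of 10 recovered reads per library on average, thinning to equal depth, and limma's voom on the recovered reads. Gene lists were put through these alternatives for 0 against 8 g/kg and not for the intermediate diets. A planned test of valine codon content was not run, since no coding sequences were used here.

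The fits were tested on simulated data with known changes at the depth of these libraries. All genes of a fraction were given the same dispersion, 0.043 for RPF and 0.00886 for total RNA, taken from well-covered genes. Genes with few reads may vary more, so the shares called may be too high for these data. Simulated sets without any effect were drawn in the same way. For total RNA, 12 of 67 changes of 2-fold, 45 of 67 of 4-fold and 57 of 66 of 8-fold were called, with 8 false calls among 10023 genes. For RPF, 0 of 65, 0 of 66 and 1 of 64 were called, and for TE 0 of 65, 0 of 65 and 6 of 63, with 4 false calls among 9158 genes. When the changed genes were drawn from those with 20 or more RPF reads, 3 of 67, 16 of 67 and 51 of 66 were called for RPF, with 16 false calls among 9486 genes. A simulated shift of -0.5 in complex I subunits was called in 6 of 20 runs for RPF, and in 0 of 20 with an estimated correlation. Figures and read recovery used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.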

Results

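Ribosome-protected fragments (RPF) and total RNA were measured in GFP-positive leukaemic cells sorted from the spleens of mice with NOTCH-ΔE T-ALL after 3 weeks on diets with 0, 0.4, 0.8 or 8 g/kg valine. Each diet had 2 libraries per fraction, T-ALL 2 and T-ALL 3, which made 16 libraries over 12012 genes. The series title ties valine supply to mitochondrial complex I, the proton-pumping NADH dehydrogenase of the respiratory chain, and the design gives ribosome occupancy relative to mRNA as translational efficiency (TE). The comparisons therefore ask which genes differ in RPF, total RNA or TE on low-valine diets.

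Reads recovered from the FPKM values were few for RPF. The T-ALL 2 RPF libraries held 80367 reads at 0 g/kg, 140641 at 0.4 g/kg, 205545 at 0.8 g/kg and 41848 at 8 g/kg. The T-ALL 3 RPF libraries held 79154, 58529, 115202 and 71432 reads in the same order of diets. The T-ALL 2 total RNA libraries held 704777, 1082650, 916047 and 1269364 reads, and the T-ALL 3 total RNA libraries 428278, 746936, 364685 and 846162 reads. In both T-ALLs the control library was thus shallower than the one at 0 g/kg for RPF and deeper for total RNA. Depth therefore differed along with diet at 0 against 8 g/kg, in opposite directions for RPF and total RNA. Genes with 0 reads made up 23.5% to 44.6% of the table per RPF library and 7.64% to 15.7% per total RNA library. The 10 most abundant genes took 5.39% to 7.79% of RPF reads and 8.04% to 9.01% of total RNA reads.

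**Figure D1:**
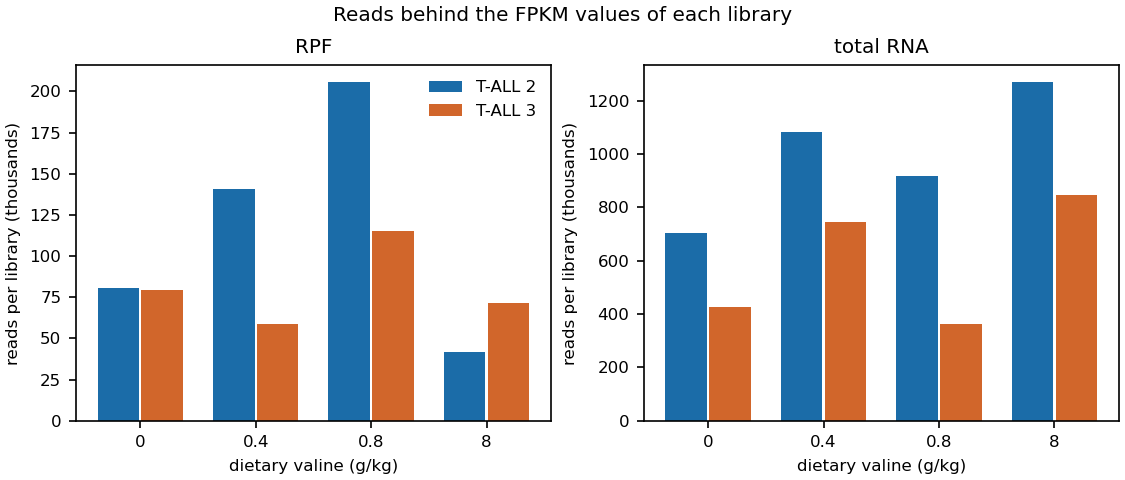
Bars show the reads behind the FPKM values of each library by dietary valine in g/kg, for RPF (left) and total RNA (right), with T-ALL 2 in blue and T-ALL 3 in orange. The shallowest RPF library, T-ALL 2 at 8 g/kg, held 41848 reads, and the deepest, T-ALL 2 at 0.8 g/kg, held 205545.

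In total RNA at 0 against 8 g/kg, Asns, the asparagine synthetase induced by amino acid shortage, had 53 ± 4.53 FPKM (SD, n = 2) against 2.70 ± 1.09, a log2 change of 4.10 ± 0.68 (SE). The mitochondrial enzyme Pck2 had 27.4 ± 3.65 against 7.34 ± 2.01 FPKM, a log2 change of 1.85 ± 0.29. The inducible chaperone gene Hspa1a had 177 ± 52.7 against 8.08 ± 5.25 FPKM, a log2 change of 4.49 ± 0.70. Its neighbour Hspa1b, with 26 and 17 reads against 0 and 0, was at least 25.9-fold higher. S100a8, a calcium-binding protein abundant in neutrophils, had 104 ± 50.8 against 3.94 ± 1.89 FPKM, a log2 change of 4.53 ± 0.69. The β-globin Hbb-bs had 8.76 ± 1.53 against 238 ± 162 FPKM, a log2 change of -4.51 ± 0.48. Each of these differences had the same sign in both T-ALLs.

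No single gene passed the test, however: limma called 0 of 10054 genes, with a lowest adjusted p of 0.0783, for Hbb-bs. The adjusted p was 0.17 for Pck2, Hspa1a, Hspa1b and S100a8 and 0.20 for Asns. At an unadjusted p under 0.05 stood 662 genes, 258 higher and 404 lower, where chance would give 502.7. In comparison, limma's voom on the recovered reads called 3 genes: Hspa1a, Pck2 and Ppp1r15a. Leaving out 1 library changed the count: 2 genes lower without the T-ALL 2 library at 0 g/kg, 1 lower without the T-ALL 3 library at 0 g/kg, and 1 lower without the T-ALL 2 control. Other genes named by rule on the higher side were Hspa1l, a close relative of Hspa1a, at 4.34 ± 0.65. The muscle-type cytochrome oxidase subunit Cox6a2 had 12 and 6 reads against 0 and 1. On the lower side stood Rab29 at -2.05 ± 0.37, Eef1akmt1 at -1.07 ± 0.21 and Ngdn at -1.07 ± 0.21. Sdhaf4, an assembly factor of complex II, had 0 and 0 reads against 6 and 3 and was at least 1.62-fold lower.

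Asns lies on chromosome 6 from 7675165 to 7693209 (GRCm38), Pck2 on chromosome 14 from 55540263 to 55550020, and S100a8 on chromosome 3 from 90669071 to 90670034. Hspa1a lies on chromosome 17 from 34969359 to 34972156, Hspa1b on the same chromosome from 34956429 to 34959238, and Hbb-bs on chromosome 7 from 103826523 to 103827928.

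Of 31 gene lists tested in total RNA at 0 against 8 g/kg, 18 passed limma's camera test, 9 higher and 9 lower. With an estimated correlation 0 passed, and the lowest adjusted p was 0.187. The ATF4 and amino acid response list, targets of the transcription factor induced when amino acids run short, rose, with a median log2 change of 0.81 (adjusted p = 4.46e-12, and adjusted p = 0.257 with an estimated correlation). Of its 25 members 23 were higher, 22 of them in both T-ALLs, and 7 passed adjusted over the list alone: Asns, Atf5, Mthfd2, Ppp1r15a, Psat1, Shmt2 and Stc2. Mthfd2 and Shmt2, enzymes of mitochondrial one-carbon metabolism, had log2 changes of 1.31 ± 0.25 and 0.75 ± 0.18, and Ppp1r15a, which directs dephosphorylation of the initiation factor eIF2α, one of 2.24 ± 0.37. ATF4 and amino acid response genes took 33.1 ± 3.1 (SD, n = 2) of 10000 total RNA reads at 0 g/kg and 21.2 ± 0.642 at 8 g/kg. In the same libraries the share of the neutrophil marker list went from 0.197 ± 0.0223 at 8 g/kg to 3.65 ± 1.46 per 10000 at 0 g/kg.

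The replication-dependent histones, which package newly copied DNA, fell in total RNA, with a median of -0.52 (adjusted p = 5.33e-17, and adjusted p = 0.414 with an estimated correlation). Of 61 histone genes 59 were lower, 51 of them in both T-ALLs, and 35 passed adjusted over the list alone. Hist2h2aa1 had 314 ± 25.4 against 573 ± 24.7 FPKM, a log2 change of -0.87 ± 0.12, and Hist1h3g one of -0.96 ± 0.16. Histones took 263 ± 8.69 of 10000 total RNA reads at 0 g/kg and 363 ± 51.2 at 8 g/kg. Immediate early genes, transcription factors and phosphatases induced within minutes of a stimulus, rose, with a median of 1.03 (adjusted p = 2.89e-06, and adjusted p = 0.416 with an estimated correlation). Of 13 immediate early genes 12 were higher, and Fos at 2.35 ± 0.59, Dusp1 at 1.64 ± 0.41 and Jun, with 82.6 ± 2.39 against 36.1 ± 8.61 FPKM, were the 3 that passed adjusted over the list alone.

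Marker lists of other blood cells moved in opposite directions. Neutrophil markers rose, with a median of 4.05 (adjusted p = 9.63e-15, and adjusted p = 0.187 with an estimated correlation). All 11 were higher, 10 of them in both T-ALLs, and 8 passed adjusted over the list alone: Camp, Elane, Ltf, Lyz2, Mpo, Ngp, Prtn3 and S100a8. Erythroid markers, genes of haemoglobin and the red cell membrane, fell, with a median of -2.36, or -1.07 with the genes at 0 reads set to their bound (adjusted p = 2.89e-06, and adjusted p = 0.257 with an estimated correlation). All 11 erythroid markers were lower, and 4 passed adjusted over the list alone, Hba-a2, Hbb-bs, Hbb-bt and Slc4a1. The median of the erythroid list was -1.46 without the T-ALL 3 library at 0 g/kg. The ATF4, histone, immediate early, neutrophil and erythroid lists kept their call without any 1 of the 4 libraries compared.

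T cell identity genes, which include the T cell receptor complex, had a median of -0.00 in total RNA, where camera pointed up (adjusted p = 0.746), and took 74.1 ± 2.86 of 10000 reads at 0 g/kg and 74.4 ± 9.07 at 8 g/kg. Macrophage markers had a median of -0.03 (adjusted p = 0.927), or 0.05 with genes at 0 reads set to their bound. Markers of B cells, natural killer cells, platelets and, in total RNA, stroma and endothelium had too few tested members for camera. Reads of B cell markers made up 0.431 ± 0.348 (SD, n = 2) of 10000 total RNA reads at 0 g/kg and 0.0473 at 8 g/kg. For natural killer cell markers the values were 4.78 ± 1.02 and 4.66 ± 0.573, for platelet markers 0.0188 and 0.0217, and for stromal and endothelial markers 10.2 ± 0.240 and 9.36 ± 0.196.

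**Figure D2:**
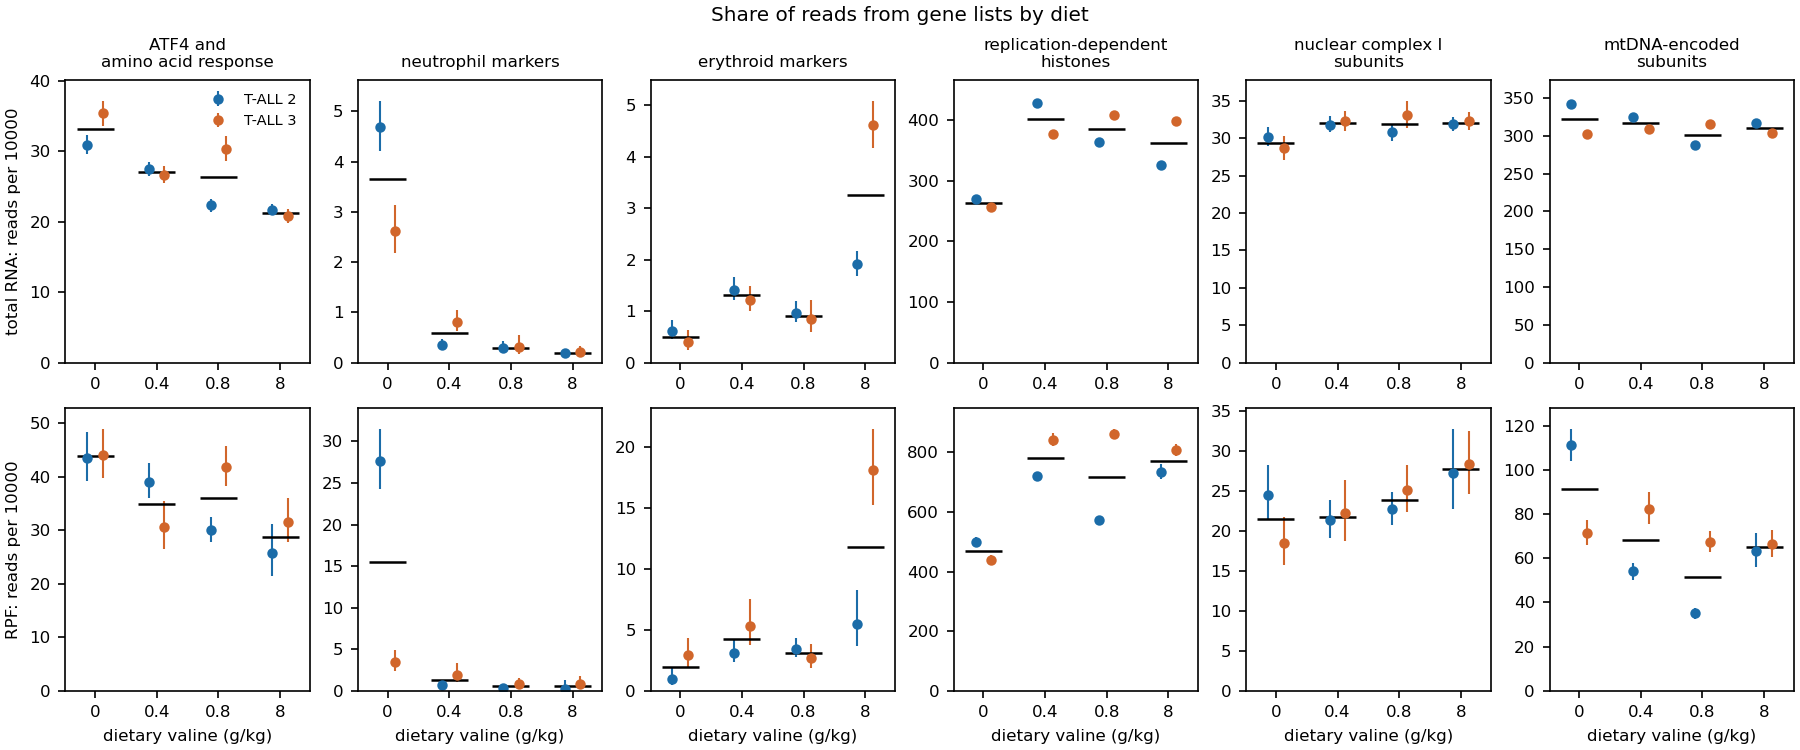
Points show reads per 10000 from 6 gene lists in each total RNA library (top) and RPF library (bottom) by dietary valine in g/kg, with T-ALL 2 in blue, T-ALL 3 in orange, vertical lines as 95% Wilson intervals and black lines as means of 2 libraries. In total RNA the ATF4 list lay at 33.1 at 0 g/kg and 21.2 at 8 g/kg, histones at 263 and 363, neutrophil markers at 3.65 and 0.197, erythroid markers at 0.504 and 3.26, and nuclear complex I subunits at 29.4 and 32.1.

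The other 13 lists that passed in total RNA had smaller medians, and each lost its call without at least 1 library. On the lower side cytosolic ribosomal proteins had a median of -0.15 with 71 of 73 members lower (adjusted p = 0.000162), and mitochondrial ribosomal proteins one of -0.15 with 58 of 77 lower (adjusted p = 0.000319). Nuclear complex IV subunits had a median of -0.35 with 11 of 12 lower (adjusted p = 0.00277), and the proteasome one of -0.21 with 30 of 38 lower (adjusted p = 0.00278). With an estimated correlation the adjusted p was 0.65 for cytosolic and 0.414 for mitochondrial ribosomal proteins, 0.416 for complex IV and 0.257 for the proteasome. Members adjusted over the list alone numbered 2 for complex IV, Cox5b at -0.86 ± 0.16 and Cox7b at -0.63 ± 0.17, and 0 for both ribosomal lists and the proteasome. At an unadjusted p under 0.05 by limma stood 14 cytosolic and 13 mitochondrial ribosomal proteins on the lower side, 1 mitochondrial ribosomal protein on the higher side, and 5 proteasome genes on the lower side. Examples were Rpl36 of the cytosolic ribosome at -0.55 ± 0.12, Mrps34 of the mitochondrial ribosome at -0.94 ± 0.22, and the proteasome subunit Psmb3 at -0.66 ± 0.16. The mitochondrial ribosomal list was drawn by symbol and holds Mrps36, at -1.89 ± 0.41, which despite its symbol belongs to the 2-oxoglutarate dehydrogenase complex. Without the T-ALL 3 library at 0 g/kg the medians were -0.05 for cytosolic ribosomal proteins (adjusted p = 0.48), and -0.13 for mitochondrial ones (adjusted p = 0.061). In that fit they were -0.18 for complex IV (adjusted p = 0.063) and -0.11 for the proteasome (adjusted p = 0.063). Without the T-ALL 2 library at 0 g/kg the medians were -0.28 for cytosolic and -0.32 for mitochondrial ribosomal proteins, and the latter had -0.26 without the T-ALL 3 control.

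Among cell cycle and stress lists, DNA replication and S phase genes had a median of 0.17 with 18 of 24 members higher in total RNA (adjusted p = 0.00628, and 0.563 with an estimated correlation). The origin licensing factor Cdc6 was among them, at 0.98 ± 0.27. Mitosis genes had a median of -0.29 with 14 of 20 lower (adjusted p = 0.0184, and 0.65 with an estimated correlation). Ccnb2 at -1.07 ± 0.24 and Cdc20 at -1.10 ± 0.27, which act in mitosis, passed adjusted over the list alone. Endoplasmic reticulum stress genes had a median of 0.19 with 15 of 19 higher (adjusted p = 0.00703, and 0.434 with an estimated correlation). Cytosolic tRNA synthetases had a median of 0.11 with 13 of 20 higher (adjusted p = 0.0174, and 0.509 with an estimated correlation), led by Cars at 1.37 ± 0.33. The interferon response had a median of 0.44 with 15 of 20 higher (adjusted p = 0.0261, and 0.627 with an estimated correlation). Heat shock genes had a median of 0.06 and a mean of 0.64 with 9 of 15 higher (adjusted p = 0.0364, and 0.475 with an estimated correlation), and Hspa1a and Hspa1b passed adjusted over the list alone. Limma called 0 members adjusted over the list alone for S phase, endoplasmic reticulum stress, tRNA synthetases and interferon response. At an unadjusted p under 0.05 stood 3, 2 and 4 higher members of the first 3 of these lists, and 1 higher and 1 lower interferon response gene. Without the T-ALL 2 library at 0 g/kg the medians were 0.07 for S phase (adjusted p = 0.53), -0.08 for mitosis (0.58), 0.07 for tRNA synthetases (0.13) and 0.04 for heat shock (0.53). Those of endoplasmic reticulum stress and interferon were 0.34 and 0.90. Without the T-ALL 3 library at 0 g/kg they were 0.08 for endoplasmic reticulum stress (adjusted p = 0.34), -0.19 for interferon (0.79), 0.32 for S phase, 0.19 for tRNA synthetases and 0.21 for heat shock. Without the T-ALL 2 control they were 0.11 for S phase (adjusted p = 0.050), 0.07 for interferon (0.87), 0.21 for heat shock (0.050), 0.32 for endoplasmic reticulum stress and 0.20 for tRNA synthetases. Without the T-ALL 3 control they were 0.23 for endoplasmic reticulum stress (adjusted p = 0.056), 0.07 for tRNA synthetases (0.095), -0.14 for mitosis (0.27) and 0.09 for heat shock (0.095).

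Notch targets, genes switched on by the receptor that drives these leukaemias, had a median of -0.35 in total RNA and did not pass (adjusted p = 0.0597). Adjusted over the list alone 2 members passed, Myc at -0.78 ± 0.15 (adjusted p = 0.27 over all genes by limma) and Heyl at -1.59 ± 0.42. Myc had 155 ± 17.1 FPKM (SD, n = 2) at 0 g/kg and 267 ± 6.93 at 8 g/kg. Complex II and III subunits at -0.15 (adjusted p = 0.0815), cholesterol synthesis at -0.22 (0.118) and neutral amino acid transporters at 0.30 (0.148) did not pass either. The same held for translation factors with TOP motifs at -0.13 (0.194), glycolysis at -0.17 (0.436), the tricarboxylic acid cycle at -0.13 (0.436) and p53 targets at 0.14 (adjusted p = 0.47). Autophagy and lysosome genes had a median of -0.12 and a mean of 0.09 (adjusted p = 0.738). Branched-chain amino acid catabolism had a median of -0.07, where camera pointed up (adjusted p = 0.927), and complex I assembly factors one of -0.07 (adjusted p = 0.953). Cholesterol synthesis passed without the T-ALL 2 library at 0 g/kg, at -0.71, and without the T-ALL 3 control, at -0.41.

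Genes of the fixed set that did not pass in total RNA included the stress regulators Atf4 at 0.69 ± 0.35, Ddit3 at 0.81 and Trib3 at 1.34. The valyl-tRNA synthetase Vars lay at 0.08, and the valine catabolic genes Bcat1 and Bckdha at 0.94 and -0.09. The amino acid transporter Slc7a5 had a log2 change of 0.47, the receptor Notch1 one of -0.27, its targets Hes1 and Dtx1 0.64 and -0.21, and the T cell receptor component Cd3e -0.34. The direction turned without 1 library for Bckdha, Dtx1 and Cd3e.

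In RPF at 0 against 8 g/kg, Hspa1a had 59 and 77 reads against 2 and 1 in the controls, a log2 change of 4.93 ± 0.81 (SE). The neutrophil genes S100a9 and Mpo were at least 13.3-fold and at least 15.4-fold higher. S100a9 had 51 reads in T-ALL 2 and 5 in T-ALL 3, Mpo had 63 and 2, and both had 0 in the controls. Cetn3, a centrin of the centrosome, had 6 and 4 reads against 0 and 0, at least 2.37-fold higher, and the mitochondrial exonuclease Rexo2 had the same counts and bound. Hbb-bs had 4 and 9 reads against 9 and 46, a log2 change of -2.30 ± 0.60. The sulphur transferase Mpst, with 0 and 0 reads against 5 and 1, was at least 3.54-fold lower. Mrpl27, of the mitochondrial ribosome, had 0 and 0 reads against 2 and 2 and was at least 2.01-fold lower. Bounds from so few reads take the counted group as exact and do not exclude a smaller fold.

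Of 9718 genes tested in RPF, limma called 0, with a lowest adjusted p of 0.0931, for Cetn3, and the adjusted p of Hspa1a was 0.30. At an unadjusted p under 0.05 stood 697 genes, 481 higher and 216 lower, where chance would give 485.9. That count was 551 of 9609 genes at equal depth and 467 of 9718 with voom. By voom on the recovered reads 6 genes passed: Hba-a2, Hist1h3f, Hspa1a, Hspa1l, Mpo and S100a9. The median log2 change of all RPF genes was 0.12, but 0.0041 at equal depth and -0.02 with voom, so its direction was not settled.

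Histones fell in RPF, with a median of -0.73 (adjusted p = 1.26e-07, and adjusted p = 0.799 with an estimated correlation). Of 58 histone genes 50 were lower, among them Hist2h2ab at -2.35 ± 0.52 and Hist1h2ac at -1.44 ± 0.40, and limma called 0 adjusted over the list alone, with 19 lower at an unadjusted p under 0.05. Their share was 470 ± 41.8 (SD, n = 2) of 10000 RPF reads at 0 g/kg and 772 ± 51.4 at 8 g/kg. The ATF4 and amino acid response list rose, with a median of 1.26, or 0.42 with the 8 members at 0 reads in both controls set to their bound (adjusted p = 0.00395, and adjusted p = 0.722 with an estimated correlation). Of its 25 members 24 were higher, and limma called 0 adjusted over the list alone, with 4 higher at an unadjusted p under 0.05. Ppp1r15a had 32 and 19 reads against 4 and 0, and Atf5 had 10 and 17 against 3 and 0. The serine synthesis enzyme Psph had 4 and 2 against 0 and 0, at least 1.42-fold higher. The median of the ATF4 list was 0.61 without the T-ALL 2 library at 0 g/kg and 0.75 without the T-ALL 3 library at 0 g/kg, both past the test. It was 0.42 (adjusted p = 0.053) over genes with an average of at least 10 reads. ATF4 genes took 43.8 ± 0.383 of 10000 RPF reads at 0 g/kg and 28.7 ± 4.12 at 8 g/kg.

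Neutrophil markers rose in RPF, with a median of 6.17, or 1.88 with the 8 members at 0 reads in both controls set to their bound (adjusted p = 7.67e-06, and adjusted p = 0.722 with an estimated correlation). All 12 were higher and 6 passed adjusted over the list alone: Ctsg, Elane, Lyz2, Mpo, Ngp and S100a9. Neutrophil markers took 27.6 of 10000 RPF reads in T-ALL 2 and 3.41 in T-ALL 3 at 0 g/kg, and 0.539 ± 0.425 (SD, n = 2) at 8 g/kg. Erythroid markers fell, with a median of -2.28, or -0.00 with genes at 0 reads in both libraries of a diet set to their bound (adjusted p = 0.000677, and adjusted p = 0.433 with an estimated correlation). Of 12 erythroid markers 10 were lower, and 2 passed adjusted over the list alone, Hbb-bs and Car2, the carbonic anhydrase of red cells. The erythroid median was -3.49 without the T-ALL 2 control.

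Among the lists that did not pass in RPF, mtDNA-encoded subunits had a median of 0.74 (adjusted p = 0.333), heat shock genes 0.18 (0.27), complex IV subunits -0.48 (0.187) and glycolysis -0.45 (0.27). Medians were 1.39 for interferon response genes (adjusted p = 0.207), 0.89 for immediate early genes (0.207) and -0.80 for macrophage markers (adjusted p = 0.187). With genes at 0 reads in both libraries of a diet set to their bound, these medians were 0.19, 0.59 and -0.57. Without the T-ALL 2 library at 0 g/kg the S phase list at -0.52, interferon response at 2.25, immediate early genes at 1.61, the proteasome at -0.36 and macrophage markers at -2.35 passed. Without the T-ALL 2 control immediate early genes at 1.83 and macrophage markers at -1.99 passed, and without the T-ALL 3 control cytosolic ribosomal proteins at -0.24. In the fixed set the log2 change in RPF was 0.22 for Atf4 and 3.36 ± 2.38 for Asns, with 9 and 2 reads against 1 and 0. For Ddit3 it was 4.17 ± 1.37, with 4 and 4 reads against 0 and 1. Further values were 0.05 for Vars, 0.82 for Bcat1, -0.36 for Bckdha, 0.63 for Slc7a5, -0.29 for Notch1, -0.32 for Myc, 0.82 for Hes1, 0.08 for Dtx1 and -0.50 for Cd3e. The direction turned without 1 library for Atf4, Hes1, Dtx1, Cd3e and Vars, and with the slope over diet order for Bcat1. Chac1 and Trib3, targets of ATF4, had 1 RPF read each at 0 g/kg and 0 in both controls, which was below the floor for a fold.

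Nuclear-encoded complex I subunits fell in RPF at 0 against 8 g/kg, with a median log2 change of -0.43, or -0.54 relative to the median of all genes (adjusted p = 0.0451 by limma's camera, and adjusted p = 0.722 with an estimated correlation). Of 36 subunits 23 were lower, 12 of them in both T-ALLs, and 13 were higher, 4 of them in both. The subunit Ndufs3 had 26.5 ± 7.56 FPKM (SD, n = 2) against 124 ± 24.7, from 3 and 2 reads against 7 and 9. Its log2 change was -2.22 ± 0.57. The subunit Ndufs7 had 0 and 5 reads against 7 and 6. Ndufs1, an iron-sulphur subunit, had 43.7 ± 8.95 FPKM against 19.5 ± 5.19, a log2 change of 1.15 ± 0.49. Ndufv1 had a log2 change of -0.38. That of Ndufb8 was -0.05, without a settled direction, since it ran from -1.22 to 1.12 without 1 library. Limma with p-values adjusted over the list alone called 0 of the 36 subunits, and at an unadjusted p under 0.05 stood 1 higher and 3 lower. The RPF share of the list was 21.5 ± 4.29 per 10000 reads at 0 g/kg, 21.8 ± 0.622 at 0.4 g/kg, 23.9 ± 1.71 at 0.8 g/kg and 27.8 ± 0.733 at 8 g/kg.

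The RPF call for complex I rested on single libraries. The median was -0.26 without the T-ALL 3 library at 0 g/kg (adjusted p = 0.37), -0.13 without the T-ALL 3 control (0.49) and -0.66 without the T-ALL 2 control (0.023). Within T-ALL 2 it was 0.07 and within T-ALL 3 it was -0.68, although the list's share of RPF reads was lower at 0 g/kg in both. The call also ended at equal depth, at -0.24 (adjusted p = 0.39), over genes with an average of at least 10 reads, at -0.38 (0.70), and with voom, at -0.46 (adjusted p = 0.073).

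In total RNA the complex I list fell, with a median of -0.16 (adjusted p = 0.0276, and adjusted p = 0.416 with an estimated correlation). In all, 29 of 36 subunits were lower, 21 of them in both T-ALLs, and limma called 0 adjusted over the list alone, with 3 lower at an unadjusted p under 0.05. Examples were Ndufa2 at -0.44 ± 0.15, Ndufb3 at -0.57 ± 0.21 and Ndufb10 at -0.39 ± 0.15, while Ndufs1, Ndufv1 and Ndufb8 lay at -0.12, -0.14 and -0.07, each with a direction that turned under another setting or without 1 library. The total RNA share was 29.4 ± 1.11 (SD, n = 2) per 10000 reads at 0 g/kg and 32.1 ± 0.320 at 8 g/kg. The call ended without the T-ALL 3 library at 0 g/kg, at -0.10 (adjusted p = 0.48), without the T-ALL 2 control, at -0.17 (0.050), and without the T-ALL 3 control, at -0.15 (adjusted p = 0.11). The median was -0.24 without the T-ALL 2 library at 0 g/kg. In TE the list had a median of -0.12 with 18 subunits higher and 18 lower (adjusted p = 0.339, and adjusted p = 0.918 with an estimated correlation), against a median of 0.20 for all genes, which was -0.08 with voom. The TE median turned to 0.04 without the T-ALL 3 library at 0 g/kg and to 0.07 without the T-ALL 3 control.

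**Figure D3:**
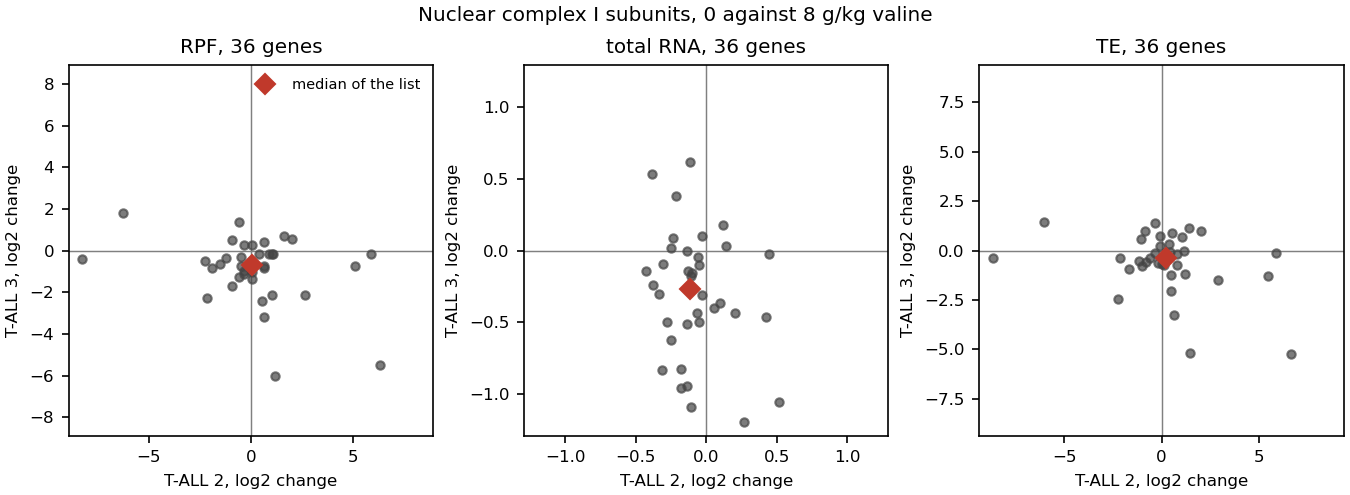
Each grey point is a nuclear-encoded complex I subunit (36 genes), with its log2 change at 0 against 8 g/kg valine in T-ALL 2 (horizontal) and T-ALL 3 (vertical) for RPF, total RNA and TE, and the red diamond is the median of the list. The diamond lies at 0.07 and -0.68 for RPF, at -0.11 and -0.27 for total RNA, and at 0.23 and -0.38 for TE, with axis ranges that differ between panels.

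Subunits encoded by mtDNA rose in total RNA, with a median of 0.15 and 9 of 13 higher (adjusted p = 0.0364, and adjusted p = 0.65 with an estimated correlation). The complex I genes mt-Nd3 at 0.81 ± 0.16, mt-Nd4l at 0.66 ± 0.12 and mt-Nd4 at 0.38 ± 0.11 passed adjusted over the list alone, while mt-Nd1 lay at -0.32. Nuclear complex V subunits, of the ATP synthase, fell in total RNA, with a median of -0.18 and 13 of 15 lower (adjusted p = 0.0364, and adjusted p = 0.509 with an estimated correlation). They also fell in RPF, with a median of -0.40 and 13 of 15 lower (adjusted p = 0.0489, and adjusted p = 0.826 with an estimated correlation). Atp5g3 at -0.48 ± 0.13 in total RNA and Atp5o at -0.96 ± 0.37 in RPF were examples. Limma called 0 complex V genes adjusted over the list alone in either fraction, with 5 lower in total RNA and 2 lower in RPF at an unadjusted p under 0.05. Sdha of complex II, Uqcrc2 of complex III, Cox4i1 of complex IV and Atp5a1 of complex V had log2 changes of 0.01, -0.18, -0.32 and -0.31 in total RNA and of -0.20, -0.03, -0.31 and -0.28 in RPF. Without 1 library the direction turned for Sdha in both fractions and for Uqcrc2 and Cox4i1 in RPF. For mtDNA-encoded subunits in total RNA the median was 0.01 without the T-ALL 2 library at 0 g/kg (adjusted p = 0.53), 0.27 without the T-ALL 3 library at 0 g/kg, 0.14 without the T-ALL 2 control (0.091) and 0.11 without the T-ALL 3 control (adjusted p = 0.11). For complex V in total RNA it was -0.14 without the T-ALL 3 library at 0 g/kg (adjusted p = 0.48), -0.39 without the T-ALL 2 library at 0 g/kg, -0.22 without the T-ALL 2 control (0.14) and -0.30 without the T-ALL 3 control (adjusted p = 0.078). For complex V in RPF it was -0.14 without the T-ALL 3 library at 0 g/kg (adjusted p = 0.62), -0.25 without the T-ALL 2 control (0.47), -0.96 without the T-ALL 2 library at 0 g/kg and -0.87 without the T-ALL 3 control.

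TE at 0 against 8 g/kg rose for 4 genes, all without RPF reads in the controls. Limma called Cetn3 (adjusted p = 0.023) and Uqcc3, Atox1 and Mrps11 (adjusted p = 0.048 each). The fitted size of such a change depends on the pseudocount and is not given. Uqcc3 is an assembly factor of complex III, Atox1 a copper chaperone and Mrps11 a protein of the mitochondrial ribosome. RPF reads at 0 g/kg were 6 and 4 for Cetn3, 3 and 2 for Uqcc3, 1 and 1 for Atox1 and 2 and 3 for Mrps11. With these reads taken as exact, RPF was at least 2.37-fold higher for Cetn3 and at least 1.19-fold higher for Uqcc3 and for Mrps11. The counting error of so few reads is not in these bounds, so smaller folds are not excluded. Atox1 was below the floor for a fold. Cetn3 lies on chromosome 13 from 81780636 to 81797155 (GRCm38), and Uqcc3 on chromosome 19 from 8880014 to 8880933. Atox1 lies on chromosome 11 from 55446637 to 55461208, and Mrps11 on chromosome 7 from 78783131 to 78792988. Next on the higher side was Rexo2 (adjusted p = 0.088 by limma). Lower TE without passing the test was seen for Psenen, a subunit of the γ-secretase that cleaves Notch, and for Mrpl27, Ppdpf, Mpst and Rgs19, all with 0 RPF reads in both libraries at 0 g/kg.

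The 4 calls in TE were among 9361 tested genes, of which 583 had an unadjusted p under 0.05 by limma where chance would give 468.05. That count was 427 of 9208 genes at equal depth and 411 of 9361 with voom, which called 0. Of all tested genes 1156 (12.3%) had 0 RPF reads in both controls. In 43 of 100 simulated sets without any effect, drawn at these depths, limma gave at least 4 TE calls. The count was 0 without either library at 0 g/kg, 4 other genes without the T-ALL 2 control and 40 without the T-ALL 3 control. Of 31 lists 0 passed in TE by limma's camera, with a lowest adjusted p of 0.231, and 0 with an estimated correlation. The S phase list passed without the T-ALL 2 library at 0 g/kg, at -0.79.

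In the fixed set TE differed by -0.47 for Atf4, -0.75 for Asns, 3.35 for Ddit3, -0.03 for Vars, -0.12 for Bcat1, -0.28 for Bckdha and 0.17 for Slc7a5 on the log2 scale. For genes of Notch signalling and T cells the TE differences were -0.03 for Notch1, 0.19 for Hes1, 0.47 for Myc, 0.29 for Dtx1 and -0.16 for Cd3e. For the respiratory chain they were 0.94 ± 0.33 for mt-Nd1, -1.01 ± 0.42 for mt-Nd5, 1.27 ± 0.59 for Ndufs1, -2.36 ± 0.57 for Ndufs3, -0.23 for Ndufv1, 0.02 for Ndufb8, -0.21 for Sdha, 0.15 for Uqcrc2, 0.01 for Cox4i1 and 0.04 for Atp5a1. Hbb-bs had a TE difference of 2.21 ± 0.55 and S100a8 one of 1.71. Under another setting or without 1 library the direction turned for every gene of this paragraph except Ddit3, Myc, Dtx1, mt-Nd1, mt-Nd5, Ndufs1, Ndufs3, Ndufv1 and Hbb-bs. For S100a8 it was -0.85 with voom and ran from -2.06 to 5.48 without 1 library.

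At 0.4 against 8 g/kg, total RNA of Hspa1a had a log2 change of 3.41 ± 0.70 (SE) and that of Hspa1l one of 3.06 ± 0.65. Hspa1b, with 11 and 12 reads against 0 and 0, was at least 9.2-fold higher. The lysozyme Lyz2 had a log2 change of 2.77 ± 0.64 and the cyclin-dependent kinase inhibitor Cdkn2d one of 1.14 ± 0.28. Asns lay at 2.46, S100a8 at 1.66 and Hbb-bs at -1.68. On the lower side stood Nkd1, an inhibitor of Wnt signalling, at -1.39 ± 0.38, Tapbpl at -1.29 ± 0.22, Sergef at -1.79 ± 0.44, Fam183b at -1.54 ± 0.39 and Tmem42, at least 1.93-fold lower. Limma called 0 of 10054 genes in total RNA, where 311 had an unadjusted p under 0.05 and the lowest adjusted p was 1, and voom called 0. Chance would give 502.7 genes at that unadjusted p, more than were seen.

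Of 31 lists 10 passed in total RNA at 0.4 g/kg, 9 higher and 1 lower, and 0 with an estimated correlation, where the lowest adjusted p was 0.653. Mitosis genes rose, with a median of 0.33 and 20 of 20 higher (adjusted p = 2.41e-05, and 0.768 with an estimated correlation). The ATF4 list rose, with a median of 0.48 and 20 of 25 higher (adjusted p = 3.77e-05, and 0.653 with an estimated correlation). Neutrophil markers rose, with a median of 1.45 (adjusted p = 9.5e-05, and 0.653 with an estimated correlation). Erythroid markers fell, with a median of -1.27 (adjusted p = 0.00499, and 0.653 with an estimated correlation). Smaller medians past the test were 0.16 for histones (adjusted p = 0.000797), 0.11 for tRNA synthetases (0.00141) and 0.19 for heat shock (0.00353). The others were 0.36 for immediate early genes (adjusted p = 0.0187), 0.21 for interferon response (0.0376) and 0.20 for endoplasmic reticulum stress (0.0486). With an estimated correlation the adjusted p of these was 0.768, except for tRNA synthetases at 0.739 and heat shock at 0.653. Within T-ALL 2 and T-ALL 3 the histone medians were 0.39 and -0.05 and those of immediate early genes -0.23 and 0.85. Adjusted over the list alone, limma called Lyz2 of the neutrophil list, Hspa1a and Hspa1b of the heat shock list, and Hsp90b1 and Pdia6 of the endoplasmic reticulum stress list.

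In RPF at 0.4 g/kg cytosolic ribosomal proteins fell, with a median of -0.39 and 56 of 73 lower (adjusted p = 0.000813, and 0.947 with an estimated correlation). The median was -0.81 within T-ALL 2 and 0.01 within T-ALL 3. In TE this list also fell, with a median of -0.35 (adjusted p = 0.014, and 0.985 with an estimated correlation), with -0.74 within T-ALL 2 and 0.05 within T-ALL 3. Macrophage markers fell in RPF, with a median of -2.20 and 8 of 10 lower (adjusted p = 0.0169, and 0.947 with an estimated correlation). In RPF the rule named Cetn3, at least 1.70-fold higher, Mrps11, at least 2.35-fold higher, and Rexo2, at least 1.07-fold higher, all with 0 reads in both controls. It also named Atox1, with 3 and 1 reads against 0 and 0, and Tmem147, with 2 and 2 against 0 and 0, both below the floor for a fold. Lower values belonged to the histone Hist1h2an at -1.56 ± 0.28, Timm13, Cd48, Haghl and Timm8b. Limma called 0 of 9718 genes in RPF (648 at an unadjusted p under 0.05, where chance would give 485.9, lowest adjusted p 0.0793). It called 0 of 9361 in TE (568 at an unadjusted p under 0.05, where chance would give 468.05, lowest adjusted p 0.0598), and voom called 0 in both. In TE the rule named Bloc1s1, of a lysosome-positioning complex, with 3 and 3 RPF reads against 0 and 0, on the higher side and H2-T22, Sppl2b, Timm13, Cd48 and Timm8b on the lower side, beside Cetn3, Atox1, Mrps11 and Tmem147. The median of all genes was 0.14 in TE at 0.4 g/kg, and -0.14 with voom. The TE count was 8 without the T-ALL 2 library at 0.4 g/kg, 3 without the T-ALL 2 control and 34 without the T-ALL 3 control.

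At 0.8 against 8 g/kg, total RNA of Pck2 had a log2 change of 1.24 ± 0.29 (SE), Ypel3 one of 1.74 ± 0.34 and Faap24, of the Fanconi anaemia pathway, one of 1.75 ± 0.40. Ciart, a repressor of the circadian clock, was at least 4.21-fold higher. Asns lay at 2.71, S100a8 at 1.22, Hspa1a at -0.01 and Hbb-bs at -2.15. On the lower side stood Sdhaf4, at least 1.79-fold lower, Tmem120a at -1.67 ± 0.35, the nucleoporin Nup35 at -2.89 ± 0.57, Milr1 at -1.55 ± 0.33 and AI413582, at least 1.36-fold lower. Limma called 0 of 10054 genes, with 347 at an unadjusted p under 0.05 and a lowest adjusted p of 1, and voom called 0. Chance would give 502.7 genes at that unadjusted p, again more than were seen. Limma called 25 genes without the T-ALL 2 library at 0.8 g/kg.

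Of the gene lists in total RNA at 0.8 g/kg 3 passed. The ATF4 list rose, with a median of 0.37 and 20 of 25 higher (adjusted p = 0.000434), and mitosis genes rose, with a median of 0.21 and 17 of 20 higher (adjusted p = 0.0023). Of 10000 total RNA reads ATF4 genes took 22.3 in T-ALL 2 and 30.3 in T-ALL 3, against 21.7 and 20.8 at 8 g/kg. Mitosis genes took 41.0 and 57.0 against 39.0 and 43.1, in the same order. Erythroid markers fell, with a median of -2.07 and 11 of 11 lower (adjusted p = 2.48e-05). With an estimated correlation the adjusted p was 0.891 for each of the 3. Adjusted over the list alone, limma called 2 genes, Hbb-bs and Hbb-bt. In RPF erythroid markers fell, with a median of -1.41 and 9 of 12 lower (adjusted p = 0.0405, and 0.875 with an estimated correlation). In TE 0 of 31 lists passed by camera. Genes named in RPF were Cetn3, at least 1.64-fold higher, Rexo2, at least 2.54-fold higher, Mrps11, at least 1.94-fold higher, and Tmem147, at least 1.49-fold higher, all with 0 reads in both controls. Atox1, with 3 and 1 reads against 0 and 0, was below the floor for a fold. On the lower side stood Ppan at -1.65 ± 0.36, Naa38 at -2.62 ± 0.57, the CD8 chain Cd8b1 at -2.18 ± 0.46, Mterf1b and Rps27l. Limma called 0 of 9718 genes in RPF, where the lowest adjusted p was 0.0813, and voom called 0. By limma 542 had an unadjusted p under 0.05, where chance would give 485.9. In TE it called 1 of 9361 genes, Cetn3 (adjusted p = 0.035), with 9 and 4 RPF reads against 0 and 0. At an unadjusted p under 0.05 stood 530 genes, where chance would give 468.05, and voom called 0. The rule added Atox1, Mrps11, Rexo2 and Tmem147 on the higher side of TE and Rgs19, Hscb, Naa38, Orai3 and Rps27l on the lower side, none past the test. The TE count was 2 other genes without the T-ALL 2 library at 0.8 g/kg, 0 without the T-ALL 3 library at 0.8 g/kg, 5 other genes without the T-ALL 2 control and 62 without the T-ALL 3 control. The median of all genes at 0.8 g/kg was 0.30 in RPF and 0.36 in TE, and -0.18 and -0.16 with voom.

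The log2 changes of T-ALL 2 and T-ALL 3, which have separate control libraries, were compared across genes, which are not independent replicates. At 0 against 8 g/kg Pearson's r was 0.145 and Spearman's rho 0.111 over 10054 genes in total RNA, and 54.2% of genes had the same sign. In RPF r was 0.0074 and rho -0.013 over 9718 genes, with 43.2% of the same sign, and in TE r was -0.012 and rho -0.027 over 9361 genes. A gene with a change of exactly 0 in only 1 T-ALL counted as not of the same sign. The rest of these shares is therefore not the share of genes that moved in opposite directions. At 0.4 g/kg r was 0.018 in total RNA, -0.014 in RPF and -0.018 in TE, and at 0.8 g/kg it was 0.0052, 0.0042 and 0.0012. The 9 comparisons describe the genes and carry no p-value.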

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

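The tests of further granulocyte genes, of erythroid markers and of simulated sets were chosen only after the result they address was seen, whereas the test on lists matched for expression and length was chosen before.

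Neutrophil markers were higher in total RNA at 0 than at 8 g/kg valine, with a median log2 change of 4.05, S100a8 at 104 FPKM and Ltf at 11.7 FPKM as examples at 0 g/kg, and 10 of the 11 tested markers with at least 1 read in a control library. Erythroid markers had a median of -2.36, or -1.07 with genes at 0 reads set to their bound. This argues against a lower share of leukaemic cells that raises every other cell type alike. A lower share together with a separate fall of erythroid RNA was not tested. Macrophage markers had a median of -0.03. B cell markers took 0.431 ± 0.348 (SD, n = 2) of 10000 total RNA reads at 0 g/kg and 0.0473 at 8 g/kg. Granulocytes carried through the sort remain a candidate explanation. Of 28 further granulocyte genes listed, 19 entries were tested, with Itgam under separate entries at 1.28 and -0.20. Their median was 2.01, where 95% of random lists matched on expression lay between -0.44 and 0.41. The median entry was Retnlg, with 3 reads at 0 g/kg and 0 at 8 g/kg, so the size of this median depends on the pseudocount. Genes with reads mainly at 0 g/kg, such as Hp with 12 against 0, can pass the expression filter through that group, which may raise the median. Of these 19, 13 were higher, 9 of them in both T-ALLs, such as Chil3 with 68 against 6 reads and Lcn2 with 23 against 5, and the GFP gate would remove granulocytes that lack GFP. Expression of these genes by leukaemic cells on a valine-free diet stays open as well and was not tested.

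The 4 TE calls at 0 against 8 g/kg all had 0 RPF reads in both controls. Chance sampling of few reads may account for a count of this size, since 43 of 100 simulated sets without any effect gave at least 4 TE calls, with up to 13, and 78 gave at least 1. A change of translation with the diet at Cetn3, Uqcc3, Atox1 and Mrps11 stays open, untested beyond these libraries.

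Nuclear complex I subunits were lower in RPF at 0 than at 8 g/kg. This result drew attention because the medians of T-ALL 2 and T-ALL 3 moved apart, at 0.074 and -0.68, a difference that was not tested. The list's share of 10000 RPF reads was lower at 0 than at 8 g/kg in both. It was 24.5 against 27.2 in T-ALL 2, where the Wilson intervals overlapped, and 18.4 against 28.3 in T-ALL 3. Chance sampling of few RPF reads cannot be told apart from an effect of the diet. In 0 of 100 simulated sets the list lay as far below all genes as the -0.54 observed. These sets, however, drew each gene independently and with the same dispersion. Thinned to equal depth, the list lay at -0.24 and did not pass (adjusted p = 0.39 by limma's camera). Expression level and gene length remain a candidate explanation, since the list's median lay at percentile 8.2 of 10000 random lists matched on both, where 95% of these lay between -0.53 and 0.25. Lower ribosome occupancy on complex I transcripts through the diet, the theme of the series, also stays open.

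DNA replication and S phase genes in total RNA had a median of 0.35 in T-ALL 2 and -0.0067 in T-ALL 3, opposite signs whose difference was not tested.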

How the results depend on the processing

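Of the alternatives, the minimum of 10 recovered reads, the thinning to equal depth and voom on recovered reads were chosen only after the data were seen. Under every alternative but the estimated correlation the ATF4, histone, immediate early, neutrophil and erythroid lists kept their direction and call in total RNA at 0 g/kg. All 3 of the genes called in total RNA by voom were higher. The T-ALL number as a covariate is the shared-number result: with it limma's TE calls went from 4 to 0 at 0 g/kg and from 1 to 0 at 0.8 g/kg, and complex I in RPF, at -0.43, no longer passed (adjusted p = 0.0502 by camera). Whether equal numbers pair libraries is open. The T-ALL 2 minus T-ALL 3 difference of each gene was taken within a diet and correlated across genes between 2 diets. Over 6 pairs of diets this correlation ran from -0.016 to 0.068 in RPF, -0.040 to 0.25 in total RNA and -0.017 to 0.052 in TE. In simulated data 0 of 66 changes of 4-fold were called in RPF and 45 of 67 in total RNA, at the depth of each fraction. All genes of a fraction had the same dispersion there, which may be too low for genes with few reads. A slope over diet order is a change per step of diet, so its size does not compare with a difference of 2 diets. For the values below the cause was not tested, except that the filter on 10 reads tests fewer genes and a left-out library leaves fewer samples.

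Counts of genes past limma's test at 0 g/kg were as follows. In RPF the main count was 0, the slope gave 1 and voom 6. In total RNA the main count was 0, the minimum of 10 reads gave 1, voom gave 3, and leaving out 1 library gave 0 to 2. In TE the main count was 4, a pseudocount of 0.1 gave 8, a pseudocount of 1 gave 1, centring on the median gave 1, and the interaction without mouse gave 12. No variance trend, the replicate block, the slope, the minimum of 10 reads, equal depth and voom each gave 0, and leaving out 1 library gave 0 to 40. For TE at 0.4 g/kg a pseudocount of 0.1 gave 5, the interaction without mouse 10, and leaving out 1 library 0 to 34. For TE at 0.8 g/kg a pseudocount of 0.1 gave 7, the interaction without mouse 16, and leaving out 1 library 0 to 62. There a pseudocount of 1, no variance trend, the replicate block, the minimum of 10 reads, equal depth and voom each gave 0. For total RNA at 0.8 g/kg leaving out 1 library gave 0 to 25.

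Counts of gene lists past camera at 0 g/kg fell to 0 with the estimated correlation in RPF and in total RNA. In RPF the minimum of 10 reads gave 2 lists and leaving out 1 library 4 to 11. In total RNA leaving out 1 library gave 10 to 14, and in TE 0 to 1. Complex I in RPF lay at -0.43 with the estimated correlation (adjusted p = 0.722), at -0.38 with the minimum of 10 reads, at -0.24 at equal depth and at -0.46 with voom, none past the test, and between -0.66 and -0.13 without 1 library. Complex I in total RNA lay at -0.16 with the estimated correlation (adjusted p = 0.416) and between -0.24 and -0.10 without 1 library. Complex I in TE lay between -0.37 and 0.069 without 1 library. The interferon response in total RNA lay between -0.19 and 0.90 without 1 library.

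Single genes that were not called turned direction as follows. In RPF the slope gave Bcat1 -0.061, and centring gave Dtx1 -0.071 and Vars -0.11. Equal depth gave Ndufb8 0.073, Sdha 0.019 and Vars -0.095 in RPF, and voom gave Vars -0.024. In total RNA equal depth gave Bckdha 0.030, Ndufv1 0.021 and Sdha -0.0090, and voom gave Ndufs1 0.0039. In TE a pseudocount of 0.1 gave Asns 0.21. Centring gave Atp5a1 -0.11, Cox4i1 -0.15 and Ndufb8 -0.13 in TE. The slope gave Atp5a1 -0.023, Cox4i1 -0.057, Ndufb8 -0.10, Notch1 0.014, Uqcrc2 -0.016 and Vars 0.0086 in TE. Equal depth gave Atf4 0.20, Cd3e 0.019, Sdha 0.028, Trib3 -2.20 and Uqcrc2 -0.63 in TE. Trib3 was below the floor for a fold in RPF, so its TE value gives no direction and is not read as a turn. With voom TE was -0.019 for Atp5a1, -0.067 for Cox4i1, -0.37 for Ndufb8, -0.85 for S100a8, -1.33 for Trib3 and -0.00993 for Uqcrc2. The voom value of Trib3 gives no direction either, for the same lack of RPF reads.

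Ranges without 1 library that crossed 0 in RPF were -0.47 to 0.92 for Atf4, -1.05 to 0.042 for Cd3e, -0.67 to 0.055 for Cox4i1, -0.42 to 0.59 for Dtx1 and -0.0050 to 1.65 for Hes1. They were -1.22 to 1.12 for Ndufb8, -0.54 to 0.15 for Sdha, -0.39 to 0.34 for Uqcrc2 and -0.40 to 0.49 for Vars. In total RNA they were -0.33 to 0.16 for Bckdha, -0.77 to 0.081 for Cd3e, -0.46 to 0.041 for Dtx1, -0.22 to 0.078 for Ndufb8, -0.47 to 0.24 for Ndufs1 and -0.20 to 0.22 for Sdha. In TE they were -2.62 to 1.12 for Asns, -1.09 to 0.15 for Atf4, -1.18 to 0.94 for Bcat1, -0.86 to 0.31 for Bckdha, -0.36 to 0.37 for Cox4i1 and -0.61 to 0.98 for Hes1. Further TE ranges were -1.30 to 1.34 for Ndufb8, -0.11 to 0.058 for Notch1, -2.06 to 5.48 for S100a8, -0.53 to 0.11 for Sdha and -0.063 to 0.39 for Slc7a5. The last were -2.17 to 3.08 for Trib3, -0.23 to 0.53 for Uqcrc2 and -0.53 to 0.47 for Vars. The range of Trib3 cannot tell a direction, since its RPF reads were below the floor for a fold.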

Other observations

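The values in this part were picked after they were seen, and no explanation of them was tested. Glycolysis genes, which turn glucose into pyruvate, took 69.4 ± 10.2 (SD, n = 2) of 10000 RPF reads at 0 g/kg and 99.9 ± 4.69 at 8 g/kg. Their median log2 change in RPF was -0.45 with 15 of 18 lower (adjusted p = 0.27 by limma's camera), although the mean was -0.01. Subunits encoded by mtDNA took 91.2 ± 28.0 of 10000 RPF reads at 0 g/kg and 64.8 ± 2.14 at 8 g/kg, against 322 ± 28.3 and 310 ± 9.55 of 10000 total RNA reads. Their median TE difference was 0.64 with 10 of 13 higher (adjusted p = 0.786 by camera). Mitochondrial ribosomal proteins had a median of 0.24 in RPF with 43 of 77 higher (adjusted p = 0.563 by camera), or 0 with genes at 0 reads in both libraries of a diet set to their bound.

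Macrophage markers took 0.549 ± 0.214 (SD, n = 2) of 10000 total RNA reads at 0 g/kg and 0.790 ± 0.538 at 8 g/kg. Natural killer cell markers took 2.75 ± 1.03 of 10000 RPF reads at 0 g/kg and 3.06 ± 0.616 at 8 g/kg. Interferon response genes went both ways in total RNA, with log2 changes of 2.88 for Usp18, which removes ISG15 from proteins, 0.61 for Isg15 and -1.21 for Ifit2, none past limma's test.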
